A study of Homo sapiens with 10 samples.

How the data were processed

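Poly(A) RNA of HSB-2 cells was sequenced in 10 libraries, 1 per sample, after Trizol extraction of total RNA and preparation with a stranded mRNA kit, per the labels' protocols. Reads were aligned with TopHat2 and counted with HTSeq on genome build hg19, per the submitters' processing notes, and the versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table holds whole-number read counts per gene for the 10 libraries, 1 column each, with no normalisation, and each column was assigned to its sample by the sample description in the labels. It has 40077 genes with Ensembl identifiers and symbols, of which 3363 had 0 reads in every library, and 895 identifiers repeat a symbol that an earlier identifier already had. All columns belonged to a sample.

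Library totals were 26332032 counts (parental), 22967470 (empty virus), 23167352 and 25683590 (wild type LDB1), 23340920 (ΔLID), 49189878 (RLIT>AAAA), 23389481 (RLEN>AAAA), 25158598 (LI>AA), 25930010 (I322A) and 20521076 (ΔLCCD). Mitochondrial genes held between 6.95% and 7.83% of the counts. TMM factors lay between 0.928 (ΔLID) and 1.03. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom over genes was 16.6 for the wild type pair and 4.45 for the closest pair, RLEN>AAAA and I322A. A share of counts for 1 library is given with an exact binomial 95% interval (Clopper-Pearson). For a gene with 0 reads in a group, folds are lower bounds from a floor of 3 counts over the group. Ratios against a group with few reads carry an exact 95% interval conditional on the total count. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

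Groups were taken from the labels. The labels name the constructs and do not say where the substitutions lie. Placing RLIT>AAAA, RLEN>AAAA, LI>AA and I322A with ΔLID as alterations of the LIM interaction domain rests on knowledge of the LDB1 protein and not on the labels, and what LCCD stands for is likewise left as the labels write it. The labels give no batch. After the data were seen, the first 5 and last 5 libraries in the order of the table were found to lie apart in more genes than under any other split 5 against 5, and these sets were added as a term to the class fit, which left 5 residual degrees of freedom. Whether the sets were prepared or sequenced apart is not known from the labels. The classes, the tests, the filter, the 20 gene lists and the rule for named genes were fixed before the data were examined.

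Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, with TMM normalisation and the quasi-likelihood F test (robust). Genes entered the test with a CPM of at least 0.412, which is 10 reads at the median library size, in at least 2 libraries. This kept 18131 genes, holding 99.9% of the counts of each library, and left out 21946. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over the genes tested. The class fit had 4 coefficients (no added LDB1, wild type LDB1, LID-altered LDB1 and ΔLCCD) and 6 residual degrees of freedom, with a common dispersion of 0.0651 and a median prior of 3.27 degrees of freedom. It pooled parental with empty virus cells and the 5 LID alterations with each other, so its spread includes differences between constructs. The per-construct fit had 9 groups and 1 residual degree of freedom, from the wild type pair, and assumed that every single library varies as that pair does. Folds of class comparisons are fitted values and not ratios of the printed means. Standard errors are the absolute log2 fold change divided by the square root of F.

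Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 20 lists. Camera with an estimated correlation and fry were the alternatives. For single constructs, camera was run with that construct as a class of its own, and the counts of called members come from the per-construct fit. For list members, calls over all genes are given beside calls adjusted over the list alone. For genes named in the text, the rule took LDB1 and the tested members of the LDB1 complex list, and up to 4 members of each list by p in the comparison described. It also took the 8 largest called rises and falls of each class comparison, with a mean CPM of at least 1 and no overlap between the libraries of the classes compared, and the 3 largest called rises and falls of each single-library comparison with a mean CPM of at least 1. Those printed are a subset of what the rule takes, and genes outside the rule are named as such.

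The steps were tested on simulated data, with 100 genes changed by a log2 fold change of 1 and 100 by 2 among 18131. The class fit recovered 27% and 70% of these for wild type against no added LDB1 (4 false calls), 36% and 82% for LID-altered against wild type (13 false calls), 35% and 82% for LID-altered against no added LDB1 (8 false calls), and 3% and 65% for ΔLCCD against wild type (3 false calls). The per-construct fit recovered 8% and 59% for ΔLID against wild type with 37 false calls, and 0% and 20% for empty virus against parental cells with 4 false calls. False calls were a larger share of all calls than the threshold of 0.05 in both LID-altered comparisons, in ΔLID against wild type and in empty virus against parental cells. The simulated libraries took each gene's spread from the class fit and held no difference between the first and last 5 libraries. The shares recovered may therefore be too high for the real libraries, and few calls there do not show that few genes differ. In the real libraries the per-construct fit called between 318 (RLEN>AAAA) and 4246 genes (ΔLID) per mutant.

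Alternatives were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 1 CPM in at least 5 libraries, a minimum absolute log2 fold change of 1, only the 2 classes compared, the per-construct fit with class means, each mutant as a class of its own, and leaving out each library in turn. Thinning the RLIT>AAAA library to the median depth, the gene lists without ΔLID, parental and empty virus cells each against the wild type pair, and the set of libraries as a term (in the class fit, with each mutant as a class of its own, and in camera) were added after the data were seen. The 3 patterns weighed in the closing section were also chosen after the data were seen. Chromosome, neighbouring genes, GC content and transcript length were taken by gene identifier from GENCODE v29, which is built on GRCh38 and not on hg19, so no coordinates are printed.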

Results

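RNA-seq read counts were compared between 10 libraries of HSB-2 cells, an established human T-cell acute lymphoblastic leukaemia line, to examine expression in cells stably expressing LDB1 or altered forms of it. LDB1 is an adaptor protein that binds LIM-domain proteins such as LMO2 through its LIM interaction domain (LID) and brings them together with TAL1 and GATA factors. Parental cells and cells carrying an empty virus formed the class with no added LDB1 (n = 2). Wild type LDB1 had n = 2. The constructs ΔLID, RLIT>AAAA, RLEN>AAAA, LI>AA and I322A, with 1 library each, formed the LID-altered class (n = 5), and ΔLCCD had 1 library. Libraries held between 20521076 counted reads (ΔLCCD) and 49189878 (RLIT>AAAA), and 18131 genes were tested. No label says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. In the class fit this spread also holds differences between parental and empty virus cells and among the 5 LID alterations. Few calls in that fit therefore do not show that few genes differ. In the order of the table, the first 5 libraries (parental, empty virus, wild type replicate 1, ΔLID and RLIT>AAAA, here the first set) lay completely apart from the last 5 (wild type replicate 2, ΔLCCD, RLEN>AAAA, LI>AA and I322A, the second set) in 2161 of 14112 genes with a mean CPM of at least 1. Chance gives 112, and the highest other of 126 splits 5 against 5 gave 530. The labels give no batch, and this split was noticed and tested only after the data were seen. With the set as a term in the class fit, 2726 genes passed for that term, so each class comparison below also has its value within sets or with the term. Levels below are in CPM, read counts scaled to a common library size with TMM factors.

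LDB1 mRNA (ENSG00000198728) was higher in all libraries given an LDB1 construct than in the others. Reads of an introduced construct are expected to count towards this gene, so a rise over no added LDB1 was set by the design. It stood at 153 CPM in parental and 144 CPM in empty virus cells, at 996 and 1430 CPM in the wild type libraries, and at 1251 CPM with ΔLCCD. The LID-altered libraries held 625 CPM (ΔLID), 631 CPM (RLIT>AAAA), 663 CPM (RLEN>AAAA), 756 CPM (I322A) and 943 CPM (LI>AA), all below both wild type libraries. A construct with a deletion is expected to give fewer reads, so the ΔLID and ΔLCCD levels are not directly comparable with the others. Relative to the mean of the libraries with no added LDB1, the levels lay between 4.21-fold (ΔLID) and 9.64-fold (wild type replicate 2). Without TMM factors, as a share of all counts, LDB1 stood at 148 CPM in parental cells (exact binomial 95% interval 144 to 153) and at 1458 CPM in wild type replicate 2 (1443 to 1472). These intervals and the floors given for genes at 0 reads cover counting error only.

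**Figure D1:**
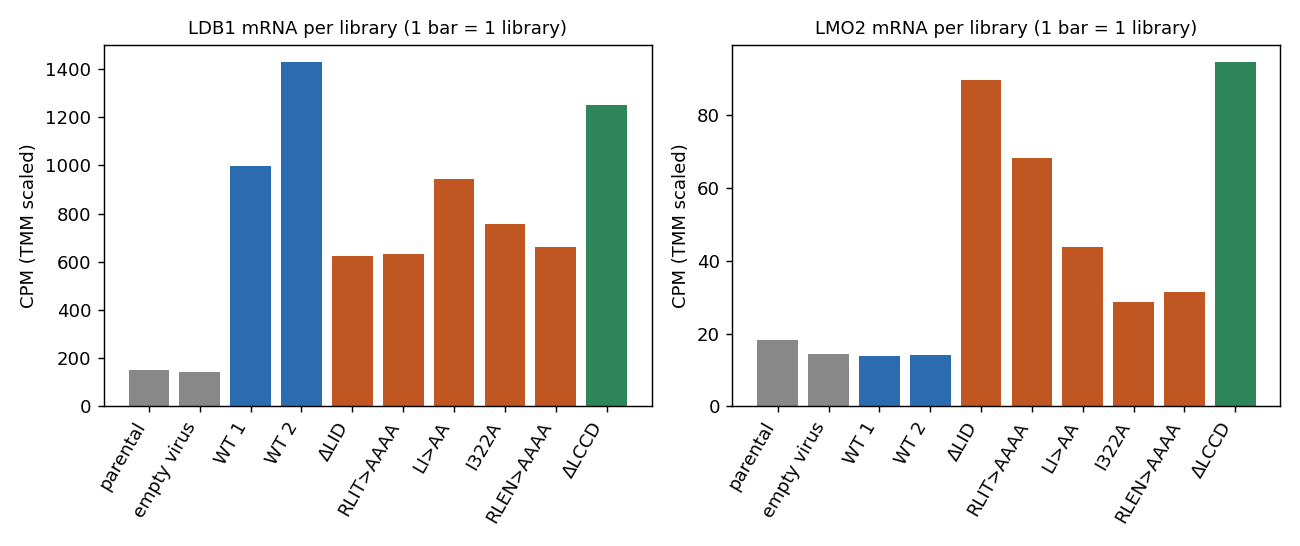
LDB1 and LMO2 levels in each of the 10 libraries, in TMM-normalised CPM on a linear axis, with 1 bar per library. LDB1 lies at 625 CPM or more in all 8 libraries with a construct and LMO2 at 28.7 CPM or more in the 6 mutant libraries, against 18.1 CPM or less in the other 4.

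The comparison of wild type LDB1 with no added LDB1 asks what added LDB1 does to expression in these cells. LDB1 itself rose 8.18-fold, from 148 ± 5.92 to 1213 ± 307 CPM (SD, n = 2 each), a log2 fold change of 3.03 (SE 0.25, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0107), and was the 1 gene called. No gene other than LDB1, the gene introduced, was called in this fit. CBFA2T3 (ENSG00000129993), a corepressor found with LDB1 and TAL1, stood at 49.7 ± 4.62 CPM without and 14.4 ± 0.944 CPM with wild type LDB1, a log2 difference of -1.79 (SE 0.45). It did not pass over all genes (edgeR adjusted p = 0.998), and together with LDB1 it passed among 21 measured genes of the LDB1 complex and its LIM partners adjusted over the list alone. LMO2 differed by -0.21 (SE 0.50). IGFBP7, an early progenitor gene, differed by -2.83 (SE 0.68) and the erythroid spectrin gene SPTB by 1.29 (SE 0.28), each the 1 member of its list that passed adjusted over the list alone, and neither passed over all genes. Of 24 measured amino acid and ER stress genes, 19 were higher with wild type LDB1, with PSAT1, PHGDH and SLC7A11 at 0.49 (SE 0.18), 0.53 (SE 0.29) and 1.08 (SE 0.63), although 0 passed over all genes and 0 adjusted over the list alone. That list ranked higher than other genes in camera (adjusted p = 0.0363), and had adjusted p = 0.977 with an estimated correlation. The other 19 lists did not pass in camera, with adjusted p from 0.0558 for NOTCH target genes, 10 of 15 higher, to 0.966, the value of the TAL1/LMO2 target genes in T-ALL, 9 of 24 higher, and of 2 other lists. Over all genes 472 had an unadjusted p under 0.05. DESeq2 called 7 genes and limma-voom 1. The LDB1 call was lost without parental (adjusted p = 0.454), without empty virus (0.265) or without wild type replicate 2 (0.0875), with the log2 fold change between 2.75 and 3.27. The second set holds no library without added LDB1, and within the first set LDB1 differed by 2.75 and CBFA2T3 by -1.85. With the set as a term LDB1 rose by 2.82 (SE 0.18, edgeR adjusted p = 0.00152) and PIM2, a kinase gene, fell by -1.26 (SE 0.13, 0.0451), while LMO2 turned to 0.27. Amino acid and ER stress genes then no longer passed in camera (adjusted p = 0.918), and proliferation genes (upwards, 1.27e-09) and hypoxia and glycolysis genes (downwards, 0.0112) did, both with adjusted p = 0.647 with an estimated correlation.

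The comparison of LID-altered with wild type LDB1 asks how alterations of the LID change the response. LDB1 mRNA was also lower in all LID-altered libraries, so over all genes the alteration and the LDB1 level cannot be told apart. GJB6 (ENSG00000121742), which encodes a gap junction connexin, fell 30.1-fold, from 18.4 ± 3.28 CPM (SD, n = 2) to 0.609 ± 0.411 CPM (SD, n = 5), a log2 fold change of -4.91 (SE 0.47, edgeR adjusted p = 0.037), and was the 1 gene called. It stood at 1.62 ± 0.359 CPM with no added LDB1 and at 1.15 CPM with ΔLCCD. LMO2 (ENSG00000135363) averaged 52.4 ± 26.1 CPM in the LID-altered libraries and 14.0 ± 0.317 CPM with wild type LDB1, a log2 difference of 1.90 (SE 0.46) in the same direction in all 5 libraries. It was also low in parental (18.1 CPM) and empty virus cells (14.3 CPM), where LDB1 mRNA was lowest. For LMO2 alone, this argues against a steady rise or fall with the LDB1 mRNA level. LMO2 and LDB1, which was lower by a log2 difference of -0.75 (SE 0.19), did not pass over all genes (edgeR adjusted p = 0.529 for both), and were the 2 of 21 complex genes that passed adjusted over the list alone. SSBP4, a single-stranded DNA binding partner of LDB1, differed by 0.60 (SE 0.21). ID2 and ID3, inhibitors of E proteins, differed by 1.20 (SE 0.40) and 0.67 (SE 0.19), IL7R by -2.47 (SE 0.73) and NOTCH3 by -1.17 (SE 0.40), and none of these 5 passed over all genes. Over all genes 1426 had an unadjusted p under 0.05. DESeq2 called 92 genes, LMO2 among them (adjusted p = 0.00405), and limma-voom 1. The GJB6 call was lost without wild type replicate 1 (adjusted p = 0.116), wild type replicate 2 (0.735), RLIT>AAAA (0.110), LI>AA (0.112) or I322A (0.165), while 2 other genes were called without wild type replicate 1. Within the first and second sets GJB6 differed by -5.22 and -4.84 and LMO2 by 2.50 and 1.25, whereas IL7R differed by 0.65 and -3.45 and so did not keep its direction. With the set as a term GJB6 was again the 1 gene called (-5.003, SE 0.43, edgeR adjusted p = 0.0411), and LMO2 had 1.82 (SE 0.33, 0.191).

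In the LID-altered libraries 7 gene lists passed in camera with a preset correlation, without any member passing over all genes. Of 30 MYC target genes, 26 were higher than with wild type LDB1, with a median log2 difference of 0.34, among them the spermidine synthase gene SRM (0.72, SE 0.22), the pyrimidine synthesis gene CAD (0.47, SE 0.17) and RRP9 (0.51, SE 0.19). The list passed in camera with a preset correlation (adjusted p = 2.53e-05), and had adjusted p = 0.472 with an estimated correlation. Of 23 p53 target genes, 17 were lower, including CCNG1 (-0.58, SE 0.16) and ZMAT3 (-0.69, SE 0.21), with camera adjusted p = 0.00253 and adjusted p = 0.472 with an estimated correlation. Of 24 immediate early genes, 16 were lower, including FOS (-1.23, SE 0.34) and FOSB (-1.78, SE 0.46), with camera adjusted p = 0.0259 and adjusted p = 0.472 with an estimated correlation. Of 32 interferon response genes, 24 were higher, including MX1 (0.65, SE 0.19) and OAS1 (1.25, SE 0.40), with camera adjusted p = 0.0302 and adjusted p = 0.472 with an estimated correlation. Amino acid and ER stress genes were lower in 18 of 24, with PSAT1 at -0.50 (SE 0.15) and SLC7A11 at -1.33 (SE 0.50), and camera adjusted p = 0.0295, which became adjusted p = 0.679 with an estimated correlation. Proliferation genes were higher in 26 of 30, with the replication gene MCM2 at 0.27 (SE 0.13) and the cyclin gene CCNE1 at 0.86 (SE 0.28), and camera adjusted p = 0.033, which became adjusted p = 0.785 with an estimated correlation. Of the 6 measured B-cell markers 3 were higher and 3 lower, with a median of -0.40 and with BLK at -1.45 (SE 0.36) the 1 member that passed adjusted over the list alone, and camera adjusted p = 0.033, which became adjusted p = 0.527 with an estimated correlation. In the other 6 lists of this paragraph 0 genes passed adjusted over the list alone. Without the ΔLID library, a check chosen after the data were seen, MYC targets (camera adjusted p = 8.75e-04), p53 targets (0.00413), immediate early genes (0.0015) and interferon genes (0.0122) still passed with the preset correlation. Amino acid and ER stress genes (0.167), B-cell markers (0.192) and proliferation genes (0.62) did not. Within the first and second sets the median differences were 0.64 and 0.08 for MYC targets, -0.43 and -0.15 for p53 targets, -0.23 and -0.33 for immediate early genes, 0.17 and 0.16 for interferon genes and -2.13 and -0.65 for B-cell markers. They were -0.75 and -0.01 for amino acid and ER stress genes and 0.42 and -0.07 for proliferation genes, so the proliferation difference did not hold in the second set. The first set holds ΔLID and RLIT>AAAA alone of the LID-altered libraries, so construct and set cannot be told apart in these medians. The 7 lists and hypoxia and glycolysis genes passed in camera with the set as a term (adjusted p from 5.24e-06 to 0.0344), with adjusted p from 0.464 to 0.716 with an estimated correlation. Between empty virus and parental cells, which differ in no LDB1 construct, 26 of 30 MYC target genes were lower in empty virus cells (camera adjusted p = 3.78e-05), which became adjusted p = 0.505 with an estimated correlation.

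**Figure D2:**
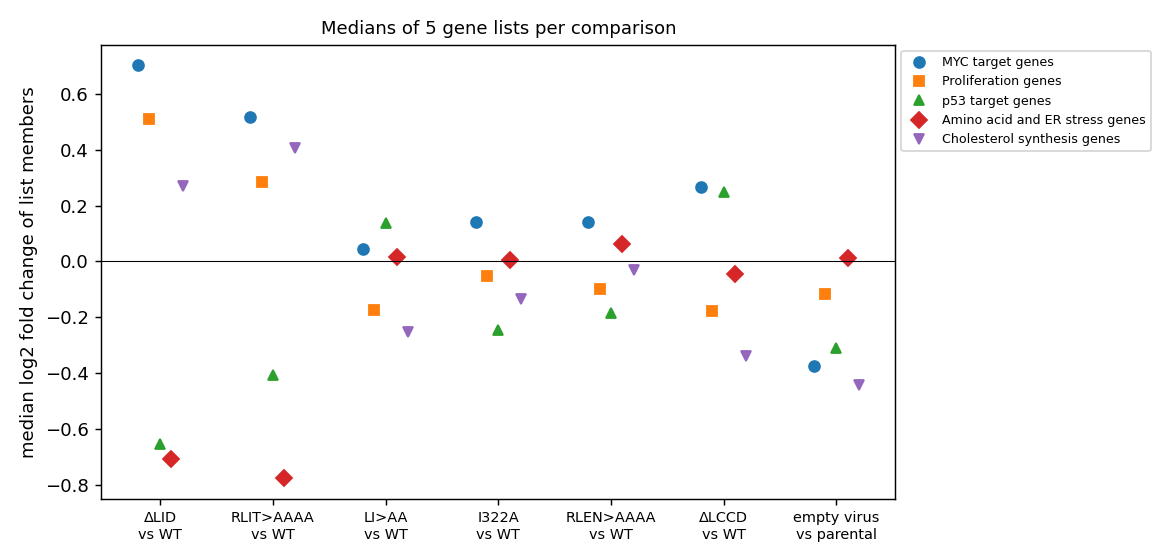
Median log2 difference of the genes of each list shown, in each construct against the wild type pair, and in empty virus against parental cells. The lists shown are MYC target, proliferation, p53 target, amino acid and ER stress, and cholesterol synthesis genes. MYC target genes have positive medians in ΔLID (0.70) and RLIT>AAAA (0.52), and a median of -0.38 in empty virus against parental cells.

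The comparison of LID-altered with no added LDB1 asks whether these constructs leave cells different from cells without added LDB1. LDB1 rose 4.88-fold, from 148 ± 5.92 CPM (n = 2) to 724 ± 134 CPM (SD, n = 5), a log2 fold change of 2.29 (SE 0.22, edgeR adjusted p = 0.0442), and was the 1 gene called, with 1254 genes at an unadjusted p under 0.05. As LDB1 is the gene introduced, a response of the cells was not shown by any gene called in this fit. LMO2 differed by 1.69 (SE 0.45, edgeR adjusted p = 0.698) and passed with LDB1 adjusted over the complex list alone. Of 30 proliferation genes, 28 were higher, with MCM2 at 0.38 (SE 0.13) and MCM7 at 0.36 (SE 0.14), and camera adjusted p = 2.01e-04, which became adjusted p = 0.689 with an estimated correlation. MYC target genes were higher in 25 of 30, with CAD at 0.50 (SE 0.17) and BOP1 at 0.57 (SE 0.21), and camera adjusted p = 8.82e-04, which became adjusted p = 0.674 with an estimated correlation. The p53 targets were lower in 15 of 23, with CCNG1 at -0.63 (SE 0.16) and ZMAT3 at -0.77 (SE 0.21), and camera adjusted p = 0.00204, which became adjusted p = 0.674 with an estimated correlation. Hypoxia and glycolysis genes were lower in 21 of 29, with BNIP3L at -0.57 (SE 0.19) and P4HA1 at -0.84 (SE 0.30), and camera adjusted p = 0.015, which became adjusted p = 0.674 with an estimated correlation. Interferon genes were higher in 22 of 32, with MX1 at 0.55 (SE 0.19) and PSMB9 at 0.41 (SE 0.15), and camera adjusted p = 0.0415, which became adjusted p = 0.54 with an estimated correlation. In these 5 lists 0 genes passed over all genes and 0 adjusted over the list alone. Without ΔLID, hypoxia and glycolysis genes had a camera adjusted p of 0.103 and 4 lists passed. The LDB1 call was lost without parental (edgeR adjusted p = 0.564), empty virus (0.236), RLIT>AAAA (0.100), RLEN>AAAA (0.146) or I322A (0.170), with library-size scaling and with the stricter filter, while DESeq2 called 45 genes and limma-voom 1. The second set holds no library without added LDB1, and within the first set LDB1 differed by 2.08, with medians of 0.45 for proliferation genes, 0.49 for MYC targets, -0.47 for p53 targets, -0.34 for hypoxia and glycolysis genes and 0.12 for interferon genes. With the set as a term LDB1 was again the 1 gene called (2.05, SE 0.16, edgeR adjusted p = 0.01004), and interferon genes no longer passed in camera (adjusted p = 0.197). The other 4 lists still passed, and amino acid and ER stress genes (0.00144), apoptosis regulators (0.00313) and B-cell markers (0.0267) passed downwards, all 7 with adjusted p from 0.405 to 0.496 with an estimated correlation.

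A reversal of the wild type response was looked for as genes called with wild type against no added LDB1 and called in the opposite direction with LID-altered against wild type LDB1. With 1 gene in each list, in edgeR 0 genes met both, where independent lists of these sizes would share 5.52e-05. The log2 fold changes of these comparisons had a correlation across genes of -0.624, and genes are not independent replicates. Both comparisons share the wild type libraries, and 100 simulations of unchanged groups gave a mean of -0.599. The covariance was -0.139, against a simulated mean of -0.121 (range -0.127 to -0.116). It lay outside that range, but the simulated libraries held no difference between the first and second sets. The excess therefore decides nothing about a reversal. GJB6, the 1 gene called for LID-altered against wild type, had levels of this shape. It stood at 1.37 and 1.87 CPM with no added LDB1, at 16.1 and 20.7 CPM with wild type, and at 0.231 to 1.23 CPM in the 6 mutants. GJB6 was not called for wild type against no added LDB1. It was picked for its fall from the same wild type libraries, so its rise is no independent evidence.

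The comparison of ΔLCCD with wild type LDB1 asks what deleting the LCCD changes. LRIF1, a chromatin factor at the inactive X chromosome, rose by a fitted 40.6-fold, with 26.8 CPM in ΔLCCD and 0.655 ± 0.153 CPM with wild type (SD, n = 2), a log2 fold change of 5.34 (SE 0.57, edgeR adjusted p = 0.0306). GALC, a lysosomal galactosidase gene, rose by 3.46 (SE 0.36, edgeR adjusted p = 0.0306) and NUDT19 by 2.93 (SE 0.36, 0.0407). The zinc finger genes ZNF486 (-2.96, SE 0.33, edgeR adjusted p = 0.0306) and ZNF493 (-2.50, SE 0.23, 0.0226) fell, as did PTRF, a coat protein of caveolae (-2.61, SE 0.30, 0.0306), and JAZF1 (-2.09, SE 0.26, 0.0407). These 3 rises and 4 falls were the 7 genes called, and reads of zinc finger genes with near-identical relatives are uncertain. LMO2 stood at 94.7 CPM, a log2 difference of 2.75 (SE 0.58, edgeR adjusted p = 0.374), and was the 1 complex gene that passed adjusted over the list alone. LDB1 differed by 0.05 (SE 0.29) and by -0.18 without wild type replicate 1. Of 25 cholesterol synthesis genes, 24 were lower, including the desaturase gene SCD (-0.71, SE 0.28), INSIG1 (-0.62, SE 0.29), FDPS (-0.60, SE 0.27) and STARD4 (-0.43, SE 0.16), with camera adjusted p = 5.31e-06 and adjusted p = 0.565 with an estimated correlation. Between empty virus and parental cells, 24 of 25 were also lower (camera adjusted p = 2.71e-07), which became adjusted p = 0.505 with an estimated correlation. The p53 targets were higher in 17 of 23, with SESN1 at 0.52 (SE 0.18) and CDKN1A at 0.80 (SE 0.37), and camera adjusted p = 0.00411, which became adjusted p = 0.578 with an estimated correlation. MYC target genes were higher in 27 of 30, with NOP2 at 0.53 (SE 0.19) and RRP9 at 0.66 (SE 0.26), and camera adjusted p = 0.00141, which became adjusted p = 0.648 with an estimated correlation. In these 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. The single ΔLCCD library was assumed to vary like the other classes, and without wild type replicate 1 or without wild type replicate 2 the count was 0. DESeq2 called 91 genes and limma-voom 6, and 849 had an unadjusted edgeR p under 0.05. The first set holds no ΔLCCD library, and against the 1 wild type library of the second set the differences were 5.003 (LRIF1), 3.50 (GALC), 2.64 (NUDT19), -2.71 (ZNF486), -2.37 (ZNF493), -2.69 (PTRF), -1.92 (JAZF1), 2.73 (LMO2) and -0.19 (LDB1). There were 20 genes called with the set as a term, the 7 among them, and LDB1 turned to -0.12. Cholesterol synthesis (camera adjusted p = 1.50e-04) and MYC target genes (7.79e-07) still passed with the term, and p53 targets (0.132) did not. Amino acid and ER stress genes (0.0016) and hypoxia and glycolysis genes (0.0142) then passed downwards, and TAL1/LMO2 target genes (0.0142) and early progenitor genes (0.0264) upwards, all 6 lists with adjusted p = 0.547 with an estimated correlation.

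Against no added LDB1, the ΔLCCD library differed in 12 genes, with 5 rises and 7 falls. LRIF1 (5.07, SE 0.56), NUDT19 (3.43, SE 0.36), GALC (3.30, SE 0.36) and LDB1 (3.08, SE 0.28) rose, as did FOXP3, the transcription factor of regulatory T cells, by 4.14 (SE 0.51, edgeR adjusted p = 0.0357) to 6.88 CPM from 0.385 ± 0.0622 CPM. The falls were ZNF486 (-2.87, SE 0.33), JAZF1 (-2.65, SE 0.26), ZNF738 (-2.62, SE 0.34), ZNF493 (-2.38, SE 0.23), PARVB (-2.24, SE 0.30), PTRF (-2.24, SE 0.29) and MTFR1 (-1.45, SE 0.18), with edgeR adjusted p from 0.0165 to 0.0435 over the 12 genes. LMO2 differed by 2.54 (SE 0.58, edgeR adjusted p = 0.439) and passed with LDB1 adjusted over the complex list alone. All 25 cholesterol synthesis genes were lower, including SCD (-0.92, SE 0.28), INSIG1 (-0.86, SE 0.29) and FDPS (-0.73, SE 0.27), with camera adjusted p = 1.21e-08 and adjusted p = 0.478 with an estimated correlation. Of 15 NOTCH target genes, 11 were higher, and NOTCH3 (3.40, SE 0.57) and GIMAP5 (0.92, SE 0.21) were the 2 that passed adjusted over the list alone, with camera adjusted p = 0.0071 and adjusted p = 0.478 with an estimated correlation. The p53 targets were higher in 19 of 23, with SESN1 at 0.48 (SE 0.18) and CDKN1A at 0.93 (SE 0.37), and camera adjusted p = 0.0071, which became adjusted p = 0.79 with an estimated correlation. In cholesterol synthesis and p53 target genes 0 passed adjusted over the list alone, and in all 3 lists 0 passed over all genes. Without parental the count of called genes was 0 and without empty virus it was 1, a gene other than the 12. DESeq2 called 118 genes and limma-voom 11, and 1101 had an unadjusted edgeR p under 0.05. No set holds both ΔLCCD and libraries without added LDB1, so no value within a set can be given. There were 6 genes called with the set as a term, LDB1, FOXP3, ZNF486, ZNF493 and JAZF1 of the 12, and ZNF826P, another zinc finger gene. The other 7 of the 12 had edgeR adjusted p from 0.0673 to 0.0790. Cholesterol synthesis genes still passed in camera (adjusted p = 1.41e-04), and NOTCH targets (0.0646) and p53 targets (0.505) did not. MYC targets (9.20e-06), TAL1/LMO2 target genes (4.73e-04) and proliferation genes (5.75e-04) then passed upwards, and hypoxia and glycolysis genes (1.41e-04) and amino acid and ER stress genes (0.0105) downwards. Without the term proliferation genes had pointed down (0.579) and amino acid and ER stress genes up (0.253). All 6 lists had adjusted p from 0.525 to 0.646 with an estimated correlation.

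Single constructs were compared with the wild type pair to describe each one. ΔLID differed in the most genes, with 2116 rises and 2130 falls, followed by RLIT>AAAA with 894 and 1267, LI>AA with 597 and 645, ΔLCCD with 420 and 497, I322A with 219 and 281, and RLEN>AAAA with 154 and 164. Empty virus against parental cells gave 285 rises and 400 falls in the same fit, more than I322A or RLEN>AAAA against wild type. With library-size scaling the ΔLID split was 1334 rises and 2765 falls, with the median log2 fold change of all genes at -0.14, and the RLIT>AAAA split was 654 and 1455. LMO2 rose in every construct, by 2.68 in ΔLID (89.7 CPM), 2.28 in RLIT>AAAA (68.2 CPM), 1.64 in LI>AA (43.7 CPM), 1.03 in I322A (28.7 CPM), 1.17 in RLEN>AAAA (31.5 CPM) and 2.75 in ΔLCCD (94.7 CPM), each with an SE of 0.21 or 0.22. It differed by -0.34 (SE 0.27, edgeR adjusted p = 0.866) between empty virus and parental cells. The spread of each single library was taken from the wild type pair alone, which has 1 library in each set, so these counts carry part of the difference between sets and no term for the set can be added to this fit. When each construct was instead a class of its own beside the other classes, edgeR called 44 genes for ΔLID, 1 for RLIT>AAAA, 7 for ΔLCCD and 0 for LI>AA, I322A and RLEN>AAAA, and LMO2 passed in none of the 6. The counts with the set as a further term were 72 for ΔLID, 20 for ΔLCCD and 0 for the other 4, with edgeR adjusted p for LMO2 at 0.0692 in ΔLID and 0.0721 in ΔLCCD. Genes with an unadjusted p under 0.05 in the single-construct fit numbered 3080 for LI>AA, 2189 for I322A and 1788 for RLEN>AAAA, where DESeq2 called 277, 81 and 28.

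**Figure D3:**
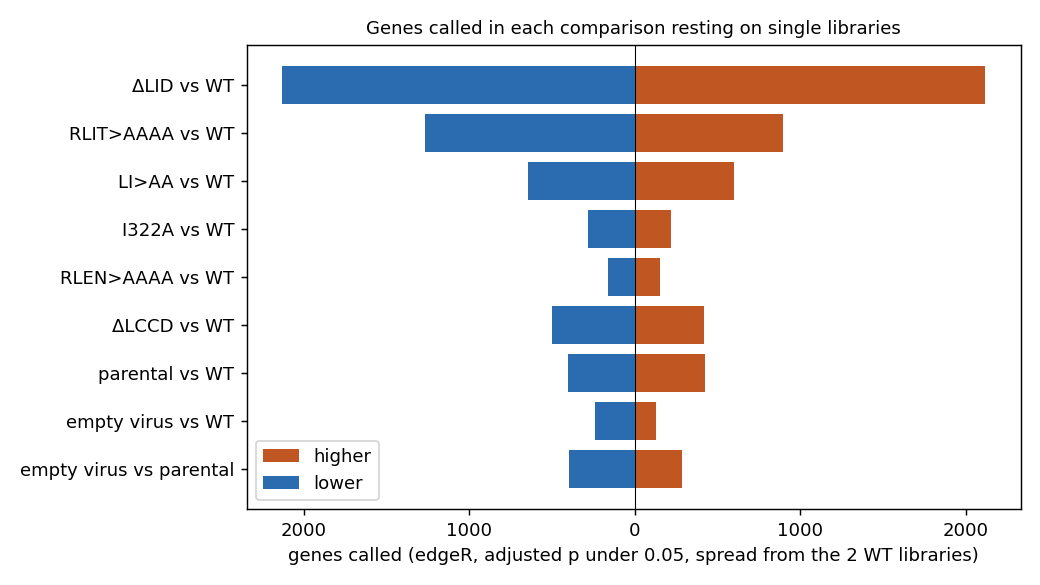
Number of genes called up and down in each comparison that rests on single libraries, with bars starting at 0. ΔLID has 2116 rises and 2130 falls, and empty virus against parental cells 285 and 400.

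The largest called rises and falls of each construct are given next. HPGDS, a prostaglandin D synthase gene, rose in ΔLID to 133 CPM against 2 reads over the wild type pair, a ratio of 3318 (95% counting interval 918 to 27408), and NUP62CL rose 114-fold (96.3 to 137). THEMIS, a T-cell signalling gene, had 0 reads in ΔLID and was at least 80.1-fold lower than wild type, from a floor of 3 counts over the group, while CRABP1 was at least 67.6-fold and KIAA1598 at least 48.5-fold lower. In RLIT>AAAA the cadherin gene CDH2 rose 188-fold (102 to 393) and the RNA-binding gene LIN28B 39.1-fold (23.1 to 72.0), and the keratin pseudogenes KRT125P and KRT126P, whose reads may be shared with relatives, were at least 70.4-fold and 68.5-fold lower, with RP11-641A6.9 at least 29.9-fold lower. In LI>AA GALNT9 rose 37.8-fold (21.3 to 74.3) and PHKA1 29.6-fold (16.1 to 60.5), while H2AFJ, GPR17 and KCTD15 were at least 15.1-fold, 13.2-fold and 9.11-fold lower. CXorf30 had 0 reads in the wild type pair and was at least 277-fold higher in I322A, 10.004-fold in ΔLID (13 reads), 3.46-fold in RLIT>AAAA and 3.23-fold in LI>AA. I322A also had rises of C20orf166-AS1 (73.2-fold, 38.1 to 162) and AC004791.2 (47.9-fold, 125 against 5 reads) and falls of KRT126P (111-fold, 19.7 to 4411), ADTRP (24.5-fold, 8.22 to 120) and GJB6 (24.1-fold, 15.5 to 39.7). RLEN>AAAA had rises of RP11-473M20.9 (114-fold, 92.6 to 142), C20orf166-AS1 (21.9-fold, 11.1 to 49.5) and HPGDS (19.1-fold, 4.58 to 170) and falls of ESPN (33.9-fold, 9.22 to 283), ADTRP (33.2-fold, 9.02 to 277) and H2AFJ (at least 13.8-fold). ΔLCCD had rises of KBTBD11 (98.0-fold, 41.3 to 305) and L3MBTL1 (32.5-fold, 21.5 to 51.5) beside LRIF1, while SCN2A, GPR125 and CDC42BPA were at least 8.88-fold, 8.60-fold and 5.97-fold lower. Differences of this kind were also present without any construct. Empty virus cells had VIPR1 higher than parental cells by 17.4-fold (9.49 to 35.5), AC004947.2 by 15.6-fold (9.25 to 28.4) and PTGDR2 by 15.4-fold (10.2 to 24.0), with ZNF521, KCTD15 and H2AFJ at least 40.9-fold, 22.3-fold and 9.45-fold lower. Differences between empty virus and parental cells compare those 2 libraries and have no replicate check, and the strand setting of the counting, which bears on antisense genes such as C20orf166-AS1, is not given in the sources used here.

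Members of the gene lists called in single constructs were counted in the per-construct fit, which called 4246 of 18131 genes for ΔLID. In ΔLID, 18 of 30 MYC target genes rose and 1 fell, 16 of 30 proliferation genes rose, 12 of 23 p53 targets fell and 2 rose, 16 of 24 amino acid and ER stress genes fell and 2 rose, 12 of 29 hypoxia and glycolysis genes fell, and 5 of 6 B-cell markers fell. Adjusted over the list alone the counts in the main direction of each list were 18, 18, 14, 17, 12 and 5. These 6 lists passed in camera (adjusted p from 3.17e-07 to 0.0338), which became adjusted p from 0.578 to 0.831 with an estimated correlation. In RLIT>AAAA, 10 MYC target genes rose and 1 fell, 16 amino acid and ER stress genes fell and 1 rose, 11 immediate early genes fell and 2 rose, and 8 p53 targets fell (19, 17, 13 and 9 in those main directions adjusted over the list alone). These 4 lists and those of proliferation, cholesterol synthesis, hypoxia and glycolysis, NF-kB and TNF response genes and apoptosis regulators passed in camera (adjusted p from 7.98e-06 to 0.00948), which became adjusted p from 0.39 to 0.468 with an estimated correlation. In RLEN>AAAA, 26 of 32 interferon genes were higher, 2 rose (5 adjusted over the list alone) and 1 fell, with camera adjusted p = 2.42e-04, which became adjusted p = 0.0815 with an estimated correlation. MYC targets, p53 targets and myeloid markers also passed in RLEN>AAAA (adjusted p from 0.0148 to 0.025), MYC targets, p53 targets and immediate early genes in I322A (0.042 for each) and TAL1/LMO2 target genes, 19 of 24 lower, in LI>AA (0.0443). All 7 lost this with an estimated correlation (adjusted p from 0.306 to 0.961).

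Called genes recurred across constructs. In all 6 constructs 49 genes were called, where 6 independent lists of these sizes would share 8.48e-04 genes. The lists are not independent, as all 6 share the wild type pair. In 20 simulations of unchanged libraries sharing that pair, a mean of 0.05 genes and at most 1 were called in all 6. The simulations held no difference between sets, and the wild type pair has 1 library in each set. Part of the excess may therefore still come from those libraries. Of the 49, 3 rose in all 6 (LMO2, ID2 and PLEKHG5) and 28 fell in all 6, among them GJB6, BLK, the transcription factor gene MAF and the cytokine receptor gene IL18R1. These genes other than LMO2, ID2, GJB6 and BLK were named after their values were seen. BLK, a Src-family kinase gene, stood at 40.2 and 50.2 CPM in the wild type libraries, 24.4 CPM in parental and 24.3 CPM in empty virus cells, and between 7.44 CPM (ΔLID) and 25.8 CPM (RLEN>AAAA) in the mutants. IL18R1 stood at 6.24 CPM in parental and 11.3 CPM in empty virus cells, and between 5.96 CPM (ΔLID) and 9.27 CPM (RLEN>AAAA) in the mutants. PLEKHG5 stood at 8.58 CPM in parental cells, above RLIT>AAAA (7.56 CPM), RLEN>AAAA (6.76 CPM) and I322A (8.09 CPM). In LMO2, ID2, GJB6 and MAF all 6 mutants lay apart from all other libraries, though narrowly in ID2, GJB6 and MAF. The nearest values were 44.3 CPM (RLIT>AAAA) and 43.9 CPM (empty virus) for ID2. They were 1.23 CPM (RLEN>AAAA) and 1.37 CPM (empty virus) for GJB6, and 51.9 CPM (RLEN>AAAA) and 52.1 CPM (parental) for MAF. MAF did not keep the order of wild type above no added LDB1 above the mutants with library-size scaling. Of the 49 genes, 25 (51.0%) were also called between empty virus and parental cells, against 0.573% of the 12568 genes called in no construct. Between single constructs and the empty virus comparison, which share no library, 484 calls were shared for ΔLID where independent lists gave 160, and 329 for RLIT>AAAA where they gave 81.6. Over the 6 constructs the odds ratios lay between 7.87 (RLIT>AAAA) and 18.2 (RLEN>AAAA). All these calls take each gene's spread from the wild type pair, so they are not independent even without a shared library. The excess over independent lists, and that of 51.0% over 0.573%, therefore decides nothing. The shared genes often moved in opposite directions: 134 of 484 moved the same way in ΔLID, 160 of 329 in RLIT>AAAA, 108 of 332 in LI>AA, 100 of 165 in I322A, 84 of 119 in RLEN>AAAA and 104 of 274 in ΔLCCD.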

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

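Of the tests below, all 4 on LMO2, the tests on the first and last 5 libraries of the table, the arrangement counts and the totals of the ordered genes after rescaling or trend removal, and the test for loss of a chromosome 19 segment were chosen only after the result was seen, and the 3 patterns were chosen after the data were seen.

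Of 35 measures tested over the 5 LID-altered libraries, 3 had 1 library far from the others, where chance gives about 5%. The RLIT>AAAA library held 49.2 M counts (M, mega), the others between 23.3 and 25.9 M. The log2 CPM of the MYC target gene RRP9 was 4.91 in ΔLID against 5.19 to 5.27 in the other 4. The log2 CPM of the p53 target gene ZMAT3 was 7.15 in LI>AA against 6.42 to 6.59 in the other 4.

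LMO2 was higher in the 6 mutant libraries than in the other 4, by a log2 difference of 1.82. Extra copies of its region would raise its neighbours too, and the 20 nearest tested genes had a median difference of 0.00812 (95% interval -0.119 to 0.0504), which argues against copies as the cause. The lowest difference over 3 scalings was 1.79, and within the first and last 5 libraries of the table the differences were 2.35 and 1.62, which argues against scaling and against the difference between these sets as the cause. For a chance arrangement, LMO2 had the smallest exact permutation p (two-sided) that 210 splits allow, 0.00952, with which no single gene can pass over 21 complex genes, so its adjusted p of 0.133 was set largely by the design and decides nothing. An effect of altered LDB1 on LMO2 mRNA may explain the pattern and was not tested, while 297 genes with a mean CPM of at least 1, LMO2 among them, lay higher in all 6 mutants (2.10%, chance 0.476%) and 180 lower (1.28%), with 8 and 15 of 210 splits giving as many, and 751 and 723 in the highest other, the first 5 libraries and ΔLCCD against the rest.

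An order of wild type above no added LDB1 above all 6 mutants was seen in 32 genes where chance gives 11.2, the opposite order in 33, and no added LDB1 above wild type above all 6 mutants in 24. Of 1260 arrangements 88 ordered as many genes, and the highest other, ΔLID and RLIT>AAAA above parental and wild type replicate 1 above the rest, ordered 417, which points to a structure of the samples, its top 4 all lying in the first 5 libraries of the table. Among 150 arrangements that keep the numbers of libraries from the first and last 5, 4 ordered as many (highest other 65), which argues against the difference between these sets as the cause and leaves chance open between the 2 counts. With library-size scaling 59.4% of the 32 kept the order, and after removal of trends with GC content and transcript length 23.3% of the 30 with a value did. Both shares met the rule set beforehand for scaling or these trends as the cause. Genes picked for an order tend to lose it when values change, so the shares decide nothing. In all, 37 and 23 genes had the order, where chance gives 11.2 and 10.9. Chance, scaling or these trends may explain the pattern, and a graded effect of LDB1 forms was not shown.

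In the ΔLCCD library 6 neighbouring chromosome 19 zinc finger genes, ZNF682, ZNF486, ZNF826P, ZNF738, ZNF493 and ZNF100, were lower than with wild type LDB1. The other 17 tested genes between the outermost of them had a median log2 change of -0.0610 (95% interval -0.117 to 0.243), which argues against loss of the whole segment, although 2 of the 17 also fell, CTD-2561J22.2 (-3.78, edgeR adjusted p = 1.36e-17) and CTD-2561J22.5 (-1.58, 0.00447). That median left out the 6 lower genes, which moves it towards 0, but genes that did not fall still outnumbered those that did. Reads moved to similar genes stay open, since other chromosome 19 zinc finger genes gained a net 125% of the lost 106 CPM, though such a gain could have other sources. Over the chromosome 8 of 216 tested zinc finger genes fell and 5 rose, and no difference from other genes was detected among falls (odds ratio 1.20, Fisher's exact test, two-sided p = 0.552). The 6 genes lay below the other 4 of the last 5 libraries of the table by a median log2 difference of -2.36, which argues against the difference between the sets as the cause, and an effect of deleting the LCCD was not told apart from a difference of this 1 library.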

How the results depend on the processing

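Thinning RLIT>AAAA, the gene lists without ΔLID, the set of libraries (first or last 5 of the table) as a term, and parental and empty virus cells each against wild type were chosen only after the data were seen. No paired analysis was possible because the groups share no replicate numbers beyond 1. The comparisons are given in the order wild type against no added LDB1, LID-altered against wild type, LID-altered against no added LDB1, ΔLCCD against wild type and ΔLCCD against no added LDB1, with 1, 1, 1, 7 and 12 genes called.

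DESeq2 called 7, 92, 45, 91 and 118 genes, which included the 1, 1, 1, 7 and 12, and limma-voom 1, 1, 1, 6 and 11, which shared 5 and 9 genes with the 7 and 12. RLE factors gave 1, 1, 1, 8 and 12. Without a filter LID-altered against wild type gave 11 genes and the ΔLCCD comparisons 24 and 29. LID-altered against no added LDB1 gave 0 with library size only and 0 with the stricter filter. With only the 2 classes compared the counts were 65, 7, 0, 901 and 13, the 13 sharing 3 genes with the 12. With the set as a term the counts were 2, 1, 1, 20 and 6, sharing 1, 1, 1, 7 and 5, and LMO2 in wild type against no added LDB1, at -0.21, reversed to 0.27. The per-construct fit gave 577, 1688, 955, 917 and 1200, with 1 residual degree of freedom. Except where samples were left out, the cause was not tested.

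Leaving out 1 library gave 0 to 1 genes for wild type against no added LDB1, with LDB1 at 2.75 to 3.27, 0 to 2 for LID-altered against wild type, 0 to 1 for LID-altered against no added LDB1, 0 for ΔLCCD against wild type and 0 to 1 for ΔLCCD against no added LDB1. A lone library was then assumed to vary like the other groups, and leaving out the ΔLCCD library leaves no comparison. The reversal count of 0 rests on lists of 1 gene each, so its value under other settings says nothing about its stability. LDB1 in ΔLCCD against wild type, at 0.05, reversed to -0.12 with the set as a term and to -0.18 without wild type replicate 1, and was 0.33 without wild type replicate 2, as the wild type libraries differ in LDB1.

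For single constructs a log2 fold change of at least 1 left 2061 genes for ΔLID, 1154 for RLIT>AAAA and 800 for LI>AA, by construction. DESeq2 called 1717 for ΔLID, 453 for RLIT>AAAA, 277 for LI>AA, 81 for I322A, 28 for RLEN>AAAA, 245 for ΔLCCD and 142 for empty virus against parental. As a class of its own ΔLID gave 44, RLIT>AAAA 1, ΔLCCD 7, and LI>AA, I322A and RLEN>AAAA 0 each, and with the set as a term 72 for ΔLID, 20 for ΔLCCD and 0 for the other 4, and the cause was not tested. RLIT>AAAA thinned to the median depth gave 1810 genes against 2161, so its depth accounts for part of its count. Parental and empty virus cells against the wild type pair gave 826 and 369. Gene lists passed in 0 cases with an estimated correlation and in 0 with the directional test of fry in all 5 comparisons. Its mixed test passed the LDB1 complex list, which holds LDB1 itself, in the 3 comparisons with no added LDB1 (adjusted p = 1.52e-05, 9.34e-05 and 3.05e-06), and NOTCH targets in ΔLCCD against no added LDB1 (0.0210). With the set as a term 2, 8, 7, 6 and 6 lists passed against 1, 7, 5, 3 and 3, and 4 lists passed for LID-altered against wild type without ΔLID.

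Over single genes and LDB1 levels, other than LDB1 in wild type against no added LDB1, 1148 results kept direction and side of the threshold, 161 lost the threshold, 63 gained it, 6 LDB1 levels moved beyond their counting interval with library size only, and 3 reversed. Over the counts and that LDB1 value, 74 counts moved beyond 1.5 times, the LDB1 value lost the threshold in 3 cases, and 83 results did neither. Depth limits genes with few reads, as shown by the floors given for genes at 0.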

Other observations

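The similarity of libraries and the 2 genes below were looked at only after the data were seen. Of 14112 genes with a mean CPM of at least 1, 184 differed more than 2-fold between RLEN>AAAA and I322A, 108 between the wild type libraries and 642 between parental and empty virus cells. ΔLID differed from the other mutants in 1038 (RLIT>AAAA) to 1925 genes (LI>AA). The first principal component held 30.7% of the variance.

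The metallothionein gene MT2A stood at 290 and 356 CPM in the wild type libraries, 33.0 CPM in ΔLID, 40.8 CPM in RLIT>AAAA and 587 CPM in LI>AA. Its level was 201 CPM in parental and 176 CPM in empty virus cells. With RLEN>AAAA, ΔLCCD and I322A it was 188, 175 and 147 CPM. The natural killer receptor gene KIR3DL2, which has close relatives with similar sequence, stood at 9.003 and 8.25 CPM with wild type LDB1, at 53.9 CPM in parental and 15.1 CPM in empty virus cells, between 24.2 CPM (I322A) and 104 CPM (ΔLID) in the LID-altered libraries, and at 4.28 CPM with ΔLCCD.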
